A study of Homo sapiens with 12 samples.

How the data were processed

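RNA was measured in 12 libraries of HEYA8, an established human ovarian cancer cell line. Cells received vehicle or colforsin daropate at 1, 5 or 10 µM for 48 h, with 3 libraries per group. Colforsin daropate is a water-soluble derivative of forskolin, which activates adenylyl cyclase and raises cyclic AMP (cAMP). The design text of the series calls the 3 libraries of a group biological replicates. The sample titles also carry a number, 6, 8 or 11, written with the prefix p, that recurs in each group. The labels do not say what it marks, so it is called the label number here. Total RNA was depleted of ribosomal RNA and made into TruSeq libraries, per the labels' protocols.

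The deposited values were variance-stabilised expression values made by the authors, on a log2 scale for abundant genes. DESeq2 and the human genome build GRCh38 (hg38) are named per the submitters' processing notes. The aligner, the counting tool and its strand setting, the annotation release and the filter on genes were not given in the sources used here. The table held 21211 entries for 12 libraries, and each column was matched to 1 library by its name. Of these, 21207 were genes and 4 named no gene (reads with no feature, ambiguous, not aligned or not unique), which stayed out of every test. A symbol was found for 21166 genes (99.8%) and a position in GENCODE 29 (GRCh38) for 20439.

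Several features of the values limit what they can show. The stabilised scale flattens towards a floor of 4.86, so a difference on it understates the fold of a low gene. Values were rounded to 3 significant digits, in steps of 0.01 under 10 and of 0.1 from 10 up, and 30.9% of the values were at 10 or above. The authors had scaled the libraries to each other before deposit, and the median value was 8.21 to 8.29 in every library. A change in total RNA per cell is therefore not visible, and changes are relative to the other genes.

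Depth was recovered from the low values, where single reads make separate steps. A stabilising curve with a dispersion of 0.0305 and an extra term of 2.55 fitted these steps with a largest residual of 0.00602. With it, 96.8% of 43694 low values matched a whole number of reads within 0.005, against 27.9% when the depths were assigned to the wrong libraries. The recovered depth was 23.9 to 48.4 megareads on genes per library, lowest in vehicle library 6. Genes took 33.9% to 36.7% of all reads. Reads with no feature made up 36.2% to 41.4%, not unique 19.3% to 25.6%, ambiguous 2.40% to 2.94% and not aligned 0.793% to 1.83%. The 10 most abundant genes took 6.51% to 11.5% of gene reads. Some of these shares moved with treatment. Against the vehicle library of the same number, the not unique share was lower in 9 of 9 treated libraries (6 of them by more than 1 rounding step). The share of the 10 most abundant genes was higher in 9 of 9 (9 by more than 1 step). The ambiguous share was higher in 9 (6 by more than 1 step), the gene share in 9 (0) and the share with no feature in 8 (2). Recovered normalised counts are printed beside the stabilised values where a fold is given, and from a value of 10 up they carry the rounding error of the deposited value.

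The main test, fixed before the data were examined together with the gene lists and the rule for named genes, was a limma moderated linear model. It used limma 3.58.1 in R 4.3.3 on the stabilised values of all 12 libraries, with 4 dose groups and a trend of the variance on the mean value. Genes entered if their value was more than 1 above the floor in at least 3 libraries, which left 17767. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and all adjusted p-values below come from limma. Each dose was compared with vehicle and with each other dose, and genes were also tested for any difference among the 4 groups and for a slope over dose rank. On simulated data the test recovered 28.6% of genes changed by 0.5 (log2) at 1 µM, 84.0% of those changed by 1 and 97.1% of those changed by 2. At 5 µM these shares were 41.0%, 82.4% and 98.6%, and at 10 µM 37.5%, 83.1% and 97.2%. False calls among 17767 simulated genes numbered 7, 12 and 6 at the 3 doses. The simulated noise was independent between genes and libraries, so these figures leave out correlation between genes and the pairing by label number.

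Gene lists were written before the data were examined. They covered CREB targets, cAMP phosphodiesterases, cAMP production and effectors, the MYC network, MYC targets, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, cell cycle inhibitors, p53 targets and apoptosis regulators. Further lists held the integrated stress response, the unfolded protein response, heat shock, cholesterol synthesis, glycolysis, the interferon response, NF-kB and cytokines, epithelial markers, mesenchymal and matrix genes, YAP/TEAD targets, SRF/MRTF and actin, MAPK output and the circadian clock. The last were ovarian carcinoma markers, ribosomal proteins, mitochondrially encoded genes, nuclear and non-coding RNA, and markers of leukocytes, endothelium and fibroblasts. Of the 31 lists, 29 kept at least 5 genes and were tested with limma's camera, which asks whether a list moved relative to all other genes. It used a preset correlation of 0.01 between genes, and p-values were adjusted over 87 tests (29 lists at 3 doses). The test was repeated with a correlation estimated per list, and calls of single genes were repeated with the adjustment over the list alone.

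Genes were named by a rule. It took MYC, the 10 largest rises and 10 largest falls at 10 µM, and the 5 largest each way at 5 µM and 1 µM, among called genes whose 3 treated libraries all lay beyond the 3 vehicle libraries. It also took the 5 largest each way between doses, and from each list described up to 4 members with the smallest adjusted p and 1 or 2 that missed the threshold. Pseudogenes and features without a symbol were passed over, and some genes that the rule names are not reported here.

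The label numbers were tested for pairing before calls were compared. The deviations from the group means were correlated across genes for the 18 pairs of libraries with the same number. These correlations were 0.316 to 0.777, all above the limit of 0.1 set beforehand, while pairs with different numbers gave -0.711 to 0.569. The 12 pairs of number 8 with number 11 gave 0.199 to 0.569, also above the limit, and all negative values were of number 6 with 8 or 11 (-0.711 to -0.287). For 9 of 12 libraries the best match had the same number. The check thus mainly set number 6 apart from 8 and 11 and parted 8 from 11 less clearly. By the limit set beforehand the numbers were taken to pair the libraries, and the fit with the label number as a replicate block is given beside results that it changes; the pairing comes from the values and the shared number, as no label states it. The first 3 principal components held 44.4%, 28.9% and 9.66% of the variance.

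The alternatives chosen beforehand were the block, other filters, an untrended or robust variance, array weights, quantile normalisation, a median shift, a fit to 2 groups only, doses in µM in place of ranks, and leaving out each library or label number. The fits that left out a library or label number used no block, so differences between label numbers stayed in their spread. Limma voom on the recovered reads with and without the block, log2 of recovered counts plus 1, a random amount within the rounding step, and the block on numbers 8 and 11 alone were added after the data had been seen. Genes on the antisense strand of another gene, and genes with a close paralog, are reported as uncertain because the handling of strand and shared reads was not given.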

Results

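Transcript levels were measured by total RNA sequencing in HEYA8 ovarian cancer cells after 48 h with vehicle or with colforsin daropate at 1, 5 or 10 µM. Each of the 4 groups held 3 libraries, numbered 6, 8 and 11 in the sample labels. Depth recovered from the deposited values was 23.9 megareads on genes in vehicle library 6 and 31.1 to 48.4 megareads in the other libraries. Expression is given on the authors' variance-stabilised log2 scale as mean ± SD with n = 3, differences are given with their standard error, and recovered normalised counts are added where a fold is printed.

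The title of the series concerns MYC-driven ovarian carcinoma, so MYC, a transcription factor that drives cell growth, was examined first. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand, GRCh38) had a level of 12.83 ± 0.21 in vehicle, 12.47 ± 0.15 at 1 µM, 12.20 ± 0.17 at 5 µM and 12.03 ± 0.38 at 10 µM (n = 3 each). Recovered counts were 7290 ± 1024, 5623 ± 591, 4669 ± 547 and 4226 ± 1036. MYC fell at 5 µM (difference -0.63 ± 0.17, limma adjusted p = 0.0309) and at 10 µM (-0.80, adjusted p = 0.00691), in 3 of 3 label numbers at each dose. With the replicate block limma gave adjusted p = 1.17e-04 at 5 µM and 1.29e-05 at 10 µM. At 1 µM the difference was -0.37 (adjusted p = 0.340, lower in 3 of 3 label numbers), and the replicate block gave adjusted p = 0.0134. Between doses the differences in MYC were -0.27 for 5 µM against 1 µM (adjusted p = 0.671), -0.17 for 10 µM against 5 µM (adjusted p = 1) and -0.43 for 10 µM against 1 µM (adjusted p = 0.179, with the block 0.00370).

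In fits that did not use the block, the call of MYC at 5 µM was lost when single libraries were left out, with adjusted p = 0.0982 without vehicle 8, 0.110 without vehicle 11, and 0.110, 0.0595 and 0.0569 without the 5 µM libraries 6, 8 and 11. Without all libraries of number 8 it was 0.240 at 5 µM and 0.0848 at 10 µM, without number 11 0.284 and 0.107, and without number 6 the difference of -0.40 at 1 µM passed the threshold (adjusted p = 0.0107).

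**Figure D1:**
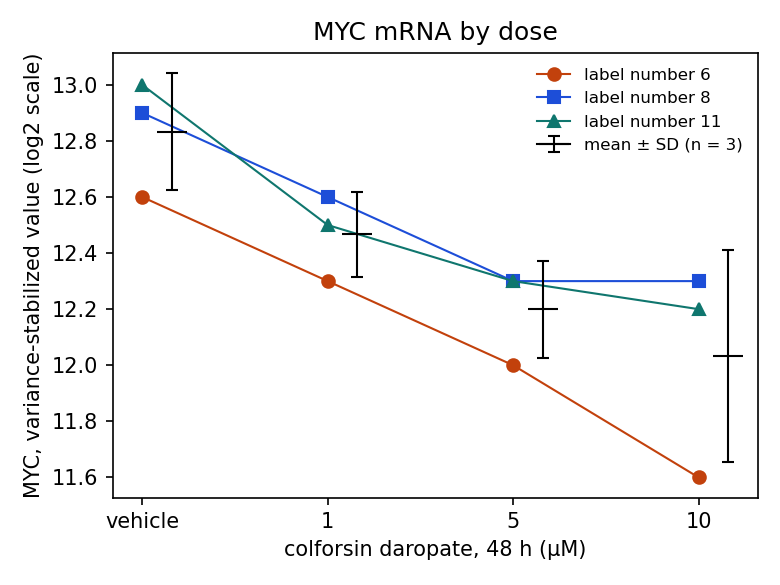
MYC expression in each of the 12 libraries (y axis, variance-stabilised log2 value) in vehicle and at 1, 5 and 10 µM colforsin daropate (x axis, µM), with points joined by label number and bars for mean ± SD (n = 3). The mean goes from 12.83 in vehicle to 12.03 at 10 µM.

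At 10 µM the largest rise on the stabilised scale was in PTGES, the terminal enzyme of prostaglandin E synthesis (chromosome 9, 129738331 to 129753047, minus strand). It went from 75.7 recovered counts in vehicle to 1905 ± 211 (n = 3), a 25.2-fold increase (3.95 ± 0.23 on the stabilised scale, limma adjusted p = 9.9e-07). PAPPA, a protease that cleaves IGF-binding proteins (chromosome 9, 116153804 to 116402322, plus strand), rose 13.9-fold, from 640 ± 161 to 8899 ± 2276 counts (3.68 ± 0.20, adjusted p = 7.46e-07). Among the named genes the count folds of SCG2 (48.3), ACKR3 (30.1) and FGFBP1 (25.5), which had low counts in vehicle, were larger than that of PTGES. Their vehicle counts were 10.5 ± 5.90, 40.9 ± 60.1 and 64.0 ± 40.8. At 10 µM they were 505 ± 259, 1232 ± 1068 and 1631 ± 898. The spread between libraries makes these folds imprecise. RDH10, which oxidises retinol (chromosome 8, 73294612 to 73325281), rose 9.47-fold to 15406 ± 2946 counts (3.23 ± 0.28, adjusted p = 2.64e-05). Other large rises were ACKR3, a scavenging chemokine receptor (3.91 ± 0.76), FGFBP1, a carrier of fibroblast growth factors (3.80 ± 0.61), LPAR1, a receptor for lysophosphatidic acid (3.63 ± 0.38), and ABCC3, an export pump for organic anions (3.59 ± 0.36). IGFBP3, an IGF-binding protein, rose by 3.48 ± 0.54 and SCG2, a secretory granule protein, by 3.35 ± 0.50. PAPPA-AS1 rose by 3.44 ± 0.18, which is uncertain because it lies within PAPPA on the opposite strand and the handling of strand was not given; the value of PAPPA carries the same uncertainty.

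The largest fall at 10 µM on the stabilised scale was in MMP1, an interstitial collagenase (chromosome 11, 102789920 to 102798160, minus strand), from 654 ± 309 to 31.4 ± 7.27 recovered counts (-3.07 ± 0.30, adjusted p = 6.16e-05). PODXL, a cell surface sialomucin (chromosome 7, 131500262 to 131558217), went from 12120 ± 1266 to 2148 ± 255 counts (-2.47 ± 0.11, adjusted p = 2.26e-07). Falls were also called for TRIM55 (-2.75 ± 0.51), KISS1, the precursor of kisspeptin (-2.65 ± 0.57), SUN3 (-2.62 ± 0.47), DEPP1 (-2.61 ± 0.78), PTPRR, a phosphatase of MAP kinases (-2.60 ± 0.23), and ESM1, a secreted proteoglycan (-2.30 ± 0.49). TNFSF15, a cytokine of the TNF family, fell by 2.21 ± 0.67 (adjusted p = 0.0338), with differences of -0.20, -3.18 and -3.26 in label numbers 6, 8 and 11. All of these genes moved the same way in 3 of 3 label numbers.

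**Figure D2:**
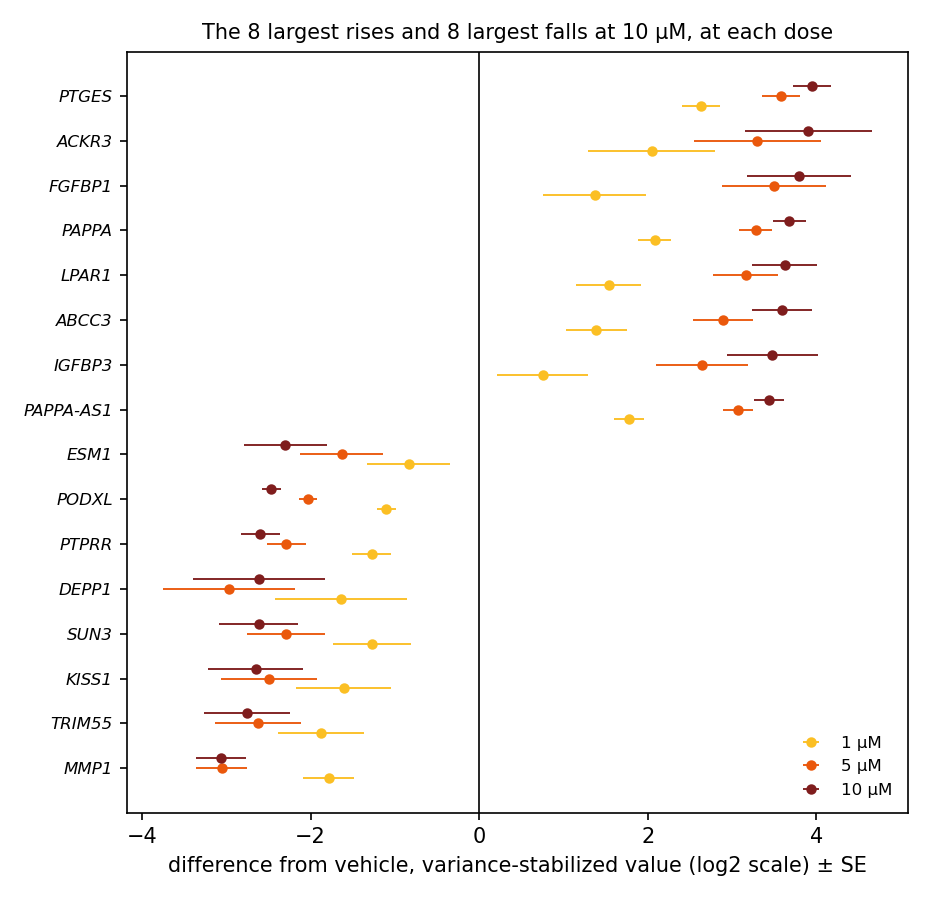
Difference from vehicle (x axis, variance-stabilised log2) at 1, 5 and 10 µM of the 8 genes with the largest rises and the 8 with the largest falls at 10 µM (y axis); points are limma estimates and bars their standard errors (n = 3 per group). At 10 µM PTGES leads the rises at 3.95 and MMP1 the falls at -3.07, and the estimates at 1 µM lie closer to 0.

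In limma's test 1982 genes were higher and 2033 lower at 10 µM than in vehicle among 17767, of which 322 rose and 231 fell by at least 1 on the stabilised scale. The replicate block gave 3326 higher and 3498 lower and kept all 4015 calls. Leaving out all libraries of a label number, in fits that did not use the block, gave 2885 higher and 3050 lower without number 6, 347 and 252 without number 8, and 468 and 494 without number 11. Without number 8 or 11 each group held number 6 beside 1 other number, and the gap between them stayed in the spread.

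Genes that answer to cAMP did not move as 1 list. Of 26 CREB targets measured, 8 rose and 4 fell at 10 µM (8 and 6 adjusted over the list alone; 10 and 6 with the block). PDE4B, a phosphodiesterase that degrades cAMP, rose by 2.45 ± 0.10, DUSP1, a MAP kinase phosphatase, by 1.80 ± 0.10 and BDNF, a growth factor, by 1.68 ± 0.17, while SGK1, a kinase, fell by 1.03 ± 0.12. NR4A3, an orphan nuclear receptor, had a difference of -0.56 (adjusted p = 0.0795, with the block 0.0275). Camera gave adjusted p = 0.251 for the list at 10 µM (median 0.13). At 5 µM 7 targets rose and 6 fell (8 and 6 adjusted over the list alone; 9 and 9 with the block). At 1 µM 3 rose and 0 fell (4 and 2 adjusted over the list alone; 7 and 3 with the block), where the list passed only without vehicle 11 (0.0448).

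Of 13 cAMP phosphodiesterases, 5 rose and 2 fell (5 and 2 adjusted over the list alone; 7 and 2 with the block; camera adjusted p = 0.264). PDE4D rose by 1.23 and PDE3A by 2.5, and PDE11A fell by 0.76. PDE7A had a difference of 0.58 (adjusted p = 0.134, with the block 3.60e-04). At 5 µM 4 phosphodiesterases rose and 2 fell (5 and 3 adjusted over the list alone; 7 and 3 with the block). At 1 µM 1 rose and 1 fell (2 and 1 adjusted over the list alone; 5 and 2 with the block). With the stricter filter camera called the phosphodiesterases higher at 1, 5 and 10 µM (adjusted p = 0.0265, 0.0417 and 0.0425), as did voom with the block at 1 and 5 µM (0.0210 and 0.0443). With the usual filter camera gave adjusted p = 0.595, 0.595 and 0.615 with an estimated correlation. Of 23 genes of cAMP production and effectors, 1 rose and 5 fell (1 and 5 adjusted over the list alone), and with the block 4 rose and 6 fell. The adenylyl cyclase ADCY3 fell by 0.82, the kinase subunit PRKAR2B by 0.78 and the anchor AKAP1 by 0.63, and the cyclase ADCY6 rose by 0.30. The inhibitor of protein kinase A PKIG had a difference of 0.23 (adjusted p = 0.0872, with the block 0.0396). This list had a median of 0.03, a mean of -0.05 and a downward test with adjusted p = 0.917.

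Ribosomal protein genes, which encode the protein part of cytosolic ribosomes, fell at 5 and 10 µM in most members, and camera called the list lower at each dose with its preset correlation but at none with an estimated one. At 10 µM 70 of 75 fell, 0 rose and 5 did not pass (71 fell adjusted over the list alone and 71 with the replicate block). At 5 µM 59 fell (71 and 71) and at 1 µM 4 fell (9 adjusted over the list alone, 49 with the replicate block). The median difference was -0.30 at 1 µM, -0.60 at 5 µM and -0.73 at 10 µM. At 10 µM RPL22 fell by 0.87 ± 0.07, RPSA by 1.17 ± 0.10, RPL7A by 0.83 ± 0.08 and RPL14 by 0.83 ± 0.09. RPS27 had a difference of -0.45 (adjusted p = 0.129, with the block 0.00428). Camera gave adjusted p = 4.81e-18, 1.2e-29 and 2.32e-29 at the 3 doses, and adjusted p = 0.615, 0.542 and 0.542 with an estimated correlation. The median at 10 µM was -0.64 with quantile normalisation and -0.72 with a median shift. Against the vehicle library of the same number, reads that were not unique took a lower share in 9 of 9 treated libraries. In 6 of them the shift was more than 1 rounding step. The 10 most abundant genes took a higher share in 9 of 9, all by more than 1 step.

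Of 60 MYC targets, a list of ribosome biogenesis and growth genes without MYC itself, 17 fell, 2 rose and 41 did not pass at 10 µM (21 and 2 adjusted over the list alone; 34 and 3 with the block). At 5 µM 7 fell and 2 rose (7 and 2 adjusted over the list alone; 21 and 3 with the block), and at 1 µM 1 fell (1 fell and 1 rose adjusted over the list alone; 6 fell and 2 rose with the block). At 10 µM FBL, the methyltransferase of ribosomal RNA, fell by 1.28 ± 0.11, the nucleolar protein NPM1 by 0.77 ± 0.09 and SORD by 0.77 ± 0.10, while ODC1, the first enzyme of polyamine synthesis, rose by 1.30 ± 0.15. MRTO4 had a difference of -0.40 (adjusted p = 0.0548, with the block 3.80e-04) and CDK4 of -0.37 (adjusted p = 0.0596, with the block 5.81e-04). The list was called lower at 5 µM (median -0.19, camera adjusted p = 0.00154) and 10 µM (-0.29, adjusted p = 2.97e-05) but with adjusted p = 0.827 and adjusted p = 0.661 with an estimated correlation. At 1 µM camera gave adjusted p = 0.202 (median -0.05), and the list passed without vehicle 6 (0.0183), the 1 µM library 8 (0.0282) or number 6 (0.0242), with voom and the block (0.0443), and in numbers 8 and 11 alone with the block (0.0336). In the MYC network, MYC and its antagonist MGA (-0.33, adjusted p = 0.0231) fell among 11 genes and 0 rose (2 and 0 adjusted over the list alone), with 4 lower and 2 higher under the block and a camera adjusted p of 0.745 at 10 µM.

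In the fit to all 12 libraries more than 50% of the genes of DNA replication fell at the highest dose. Of 45 G1/S genes, 28 fell, 1 rose and 16 did not pass at 10 µM (36 and 1 adjusted over the list alone; 41 and 1 with the block). The sliding clamp PCNA fell by 0.57 ± 0.06, and the helicase subunits MCM5 and MCM6 by 0.84 ± 0.11 and 0.80 ± 0.11, while the kinase CDK2 rose by 0.77 ± 0.09. ORC1 had a difference of -0.89 (adjusted p = 0.0559, with the block 0.00371) and TK1 of -1.11 (adjusted p = 0.0632, with the block 0.00667). The list median at 10 µM was -0.70 (camera adjusted p = 4.18e-12; adjusted p = 0.615 with an estimated correlation). It was -1.29 in label number 6 and -0.40 in both 8 and 11. Without number 6, 22 of the 45 genes fell and 1 rose at 10 µM. At 5 µM 5 fell and 1 rose (5 and 1 adjusted over the list alone; 11 and 1 with the block), with a median of -0.27 (camera adjusted p = 9.02e-04; adjusted p = 0.896 with an estimated correlation), and this call was lost without vehicle 6 (adjusted p = 0.396) or with array weights (0.0538). At 1 µM 1 rose (1 adjusted over the list alone), with camera adjusted p = 0.460, and the list was called higher with array weights (0.0397) and without vehicle 6 (1.22e-04), the 1 µM library 11 (0.0144) or number 6 (0.0175).

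Genes of mitosis moved apart between the label numbers. Of 34 G2/M genes, 0 passed limma's test at any dose, by the adjustment over all genes or over the list alone, with 1, 0 and 0 at an unadjusted p under 0.05 at 1, 5 and 10 µM and 0 called by voom. With the block 0, 1 and 1 rose. CDC25B, a phosphatase that activates the mitotic kinase, had a difference of 0.46 (adjusted p = 0.235, with the block 0.0400) at 10 µM and AURKB, a mitotic kinase, of -0.70 (adjusted p = 0.333). In vehicle the list median was 11.2 in library 6, 9.20 in library 8 and 8.80 in library 11, so library 6 stood apart among the vehicle libraries. The list median of differences at 10 µM was -1.94 in label number 6, 0.31 in number 8 and 0.41 in number 11, and without number 6 14, 15 and 9 members rose at 1, 5 and 10 µM and 0 fell. At 1 µM camera called the list higher (median 0.39, adjusted p = 0.0295; adjusted p = 0.896 with an estimated correlation); the call was lost with the stricter filter (0.0706) or 2 groups only (0.0973), and without vehicle 8 (0.553), vehicle 11 (0.932), the 1 µM library 6 (0.947), number 8 (0.298) or number 11 (0.150). At 5 and 10 µM camera gave adjusted p = 0.610 and 0.309. The list was called higher at 5 µM with array weights (1.01e-04) and without vehicle 6 (7.05e-07) or number 6 (7.29e-07). At 10 µM it was called lower without vehicle 8 (0.0293), vehicle 11 (0.00238), number 8 (0.0282) or number 11 (0.00710), and higher without number 6 (0.00199).

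The 29 replication-dependent histone genes, which are expressed in S phase, followed the same division. Limma called 0 of them at any dose, over all genes or over the list alone, with 0, 0 and 1 at an unadjusted p under 0.05 at 1, 5 and 10 µM and 0 called by voom. With the block 4 fell at 10 µM. H2BC5 had a difference of -0.70 at 10 µM (adjusted p = 0.0934, with the block 0.00536) and H4C4 of -0.60 (adjusted p = 0.224, with the block 0.0231). The median at 10 µM was -1.57 in number 6, 0.26 in number 8 and 0.30 in number 11, and without number 6 14, 10 and 6 members rose at 1, 5 and 10 µM. The list was called higher at 1 µM (median 0.40, camera adjusted p = 0.0306; adjusted p = 0.896 with an estimated correlation), and this was lost with the stricter filter (0.0706) or 2 groups only (0.106), and without vehicle 8 (0.553), vehicle 11 (0.887), the 1 µM library 6 (0.947), number 8 (0.368) or number 11 (0.0809). Camera gave adjusted p = 0.917 at 5 µM, where the list passed upward with array weights (0.0196) and without vehicle 6 (9.3e-05) or number 6 (3.32e-04). At 10 µM the value was 0.197, and it passed downward without vehicle 8 (0.0155), vehicle 11 (0.00238), number 8 (0.0141) or number 11 (0.00614) and upward without number 6 (0.0242).

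**Figure D3:**
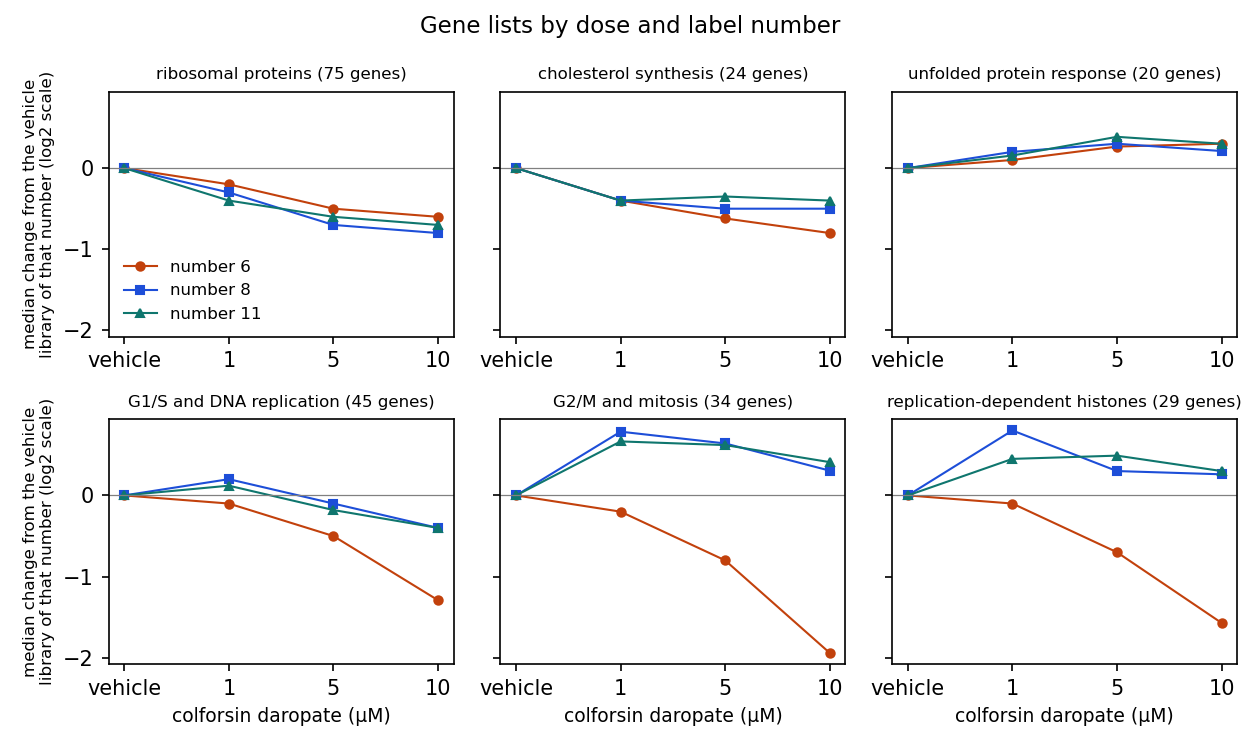
Median difference of 6 gene lists from the vehicle library of the same label number (y axis, variance-stabilised log2) in vehicle and at 1, 5 and 10 µM (x axis), with 1 line per label number and 1 library per point. At 10 µM the G2/M list is at -1.94 in number 6, 0.31 in number 8 and 0.41 in number 11, while the ribosomal protein list is below 0 in all 3.

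Enzymes of cholesterol synthesis fell in part, and camera called the list lower at each dose with its preset correlation but at none with an estimated one. Of 24 genes, 4 fell at 1 µM (13 adjusted over the list alone; 12 with the block), 11 at 5 µM (15 fell and 1 rose adjusted over the list alone; 18 and 1 with the block), and 13 fell and 1 rose at 10 µM (17 and 1 adjusted over the list alone; 19 and 1 with the block). HMGCS1, the first committed enzyme, fell by 1.20 ± 0.07, the squalene epoxidase SQLE by 0.87 ± 0.10 and FDPS by 0.57 ± 0.09 at 10 µM. NSDHL had a difference of -0.22 (adjusted p = 0.0580, with the block 0.0240). Medians were -0.40, -0.52 and -0.58 (camera adjusted p = 2.69e-13, 6.81e-10 and 2.61e-08), with adjusted p = 0.397 with an estimated correlation at each dose.

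Some chaperones and degradation factors of the unfolded protein response rose, and camera called the list higher at each dose with its preset correlation but at none with an estimated one. Of 20 genes, 1 rose at 1 µM (3 adjusted over the list alone; 5 with the block), 7 at 5 µM (12 and 12) and 7 at 10 µM (7 adjusted over the list alone; 11 higher and 1 lower with the block), and 0 fell in limma's unblocked test. DNAJC3 rose by 0.43 ± 0.06, DERL1 by 0.37 ± 0.07, the protein disulphide isomerase PDIA4 by 0.33 ± 0.07 and CRELD2 by 0.39 ± 0.09 at 10 µM. HYOU1 had a difference of 0.60 (adjusted p = 0.114, with the block 9.09e-04) and XBP1, a transcription factor of this response, of 0.43 (adjusted p = 0.118, with the block 1.86e-04). Medians were 0.20, 0.31 and 0.20 (camera adjusted p = 9.02e-04, 1.73e-04 and 0.00418), and adjusted p = 0.397, 0.397 and 0.542 with an estimated correlation.

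Among 27 p53 targets, 8 fell, 1 rose and 18 did not pass at 10 µM (11 and 1 adjusted over the list alone; 15 and 2 with the block). CCNG1 fell by 0.70 ± 0.09, the phosphatase PPM1D by 0.47 ± 0.09 and the ribonucleotide reductase subunit RRM2B by 0.70 ± 0.15, while TIGAR, a regulator of glycolysis, rose by 1.00 ± 0.13. FDXR had a difference of -0.57 (adjusted p = 0.0730, with the block 0.0201) and BAX of -0.27 (adjusted p = 0.0745, with the block 0.0108). At 5 µM 5 fell and 1 rose (6 and 1 adjusted over the list alone; 14 and 1 with the block), and at 1 µM limma called 0, with 10 at an unadjusted p under 0.05 and 2 lower by voom (5 fell adjusted over the list alone; 6 fell and 1 rose with the block). The list was called lower at 1, 5 and 10 µM (medians -0.27, -0.23 and -0.23; camera adjusted p = 1.22e-04, 9.02e-04 and 0.00287), with adjusted p = 0.595, 0.615 and 0.615 with an estimated correlation. Of 26 apoptosis regulators 3 rose and 3 fell at 10 µM (3 and 3 adjusted over the list alone; 6 and 10 with the block; camera adjusted p = 0.419). BCL2 and BCL2L1, which protect against apoptosis, fell by 1.04 ± 0.14 and 1.17 ± 0.25 and the promoter of apoptosis BIK by 0.69 ± 0.15. Of 15 cell cycle inhibitors 2 rose and 3 fell (2 and 3 adjusted over the list alone; 4 and 5 with the block; camera adjusted p = 0.682), with the CDK inhibitor CDKN1C higher by 2.24 and TOB1 lower (-0.64). RB1 was at 0.27 (adjusted p = 0.127, with the block 0.00445). Without number 6, 20 of the p53 targets fell and 1 rose at 10 µM.

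Part of the mesenchymal and matrix genes rose, and the call of the list depended on the setting and passed at no dose with an estimated correlation. Of 30 genes, 12 rose and 3 fell at 10 µM (13 and 4 adjusted over the list alone; 15 and 6 with the block), 8 and 2 at 5 µM (13 and 3 adjusted over the list alone; 14 and 4 with the block), and 2 and 0 at 1 µM (4 and 0 adjusted over the list alone; 13 and 0 with the block). Fibronectin (FN1) rose by 1.93 ± 0.30, N-cadherin (CDH2) by 1.30 ± 0.19, the collagen crosslinking enzyme LOXL2 by 0.93 ± 0.17 and collagen IV (COL4A1) by 0.67 ± 0.08. LOX had a difference of 0.67 (adjusted p = 0.0973, with the block 1.83e-04). Camera gave adjusted p = 0.00922, 0.151 and 0.0331 at 1, 5 and 10 µM (medians 0.21, 0.23 and 0.43), the block 0.0115 at 5 µM, and adjusted p = 0.615, 0.827 and 0.632 with an estimated correlation. The call at 10 µM was lost with quantile normalisation (0.108), the stricter filter (0.0562), and without vehicle 8 (0.0557), vehicle 11 (0.0527), the 10 µM library 6 (0.102) or number 11 (0.0543). At 5 µM the list passed without vehicle 6 (0.0418) or number 6 (0.0166).

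Among markers of other cell types, 3 of 8 endothelial genes fell at 5 and at 10 µM and 0 rose (3 adjusted over the list alone; 4 with the block), and 1 fell at 1 µM (2 and 2). ROBO4 fell by 1.98 ± 0.20, ESAM by 0.80 ± 0.12 and VWF by 0.84 ± 0.18. TIE1 was at -0.30 (adjusted p = 0.131, with the block 0.00598) and KDR at -0.27 (adjusted p = 0.456). Camera called the list lower at 5 and 10 µM (adjusted p = 0.0415 and 0.0448; adjusted p = 0.397 with an estimated correlation), and the block gave 0.0615 at both. Both calls were lost with the stricter filter (0.110 and 0.118), array weights (0.171 at both), 2 groups only (0.0534 and 0.0552), voom (0.0916 at both) and log2 of recovered counts (0.0501 and 0.0578). They were also lost without vehicle 6 (0.163 and 0.157) or number 6 (0.231 and 0.314), at 5 µM without the 5 µM library 11 (0.0979) or number 11 (0.0662), and at 10 µM without the 10 µM library 11 (0.0642), and at 1 µM (adjusted p = 0.154) the list passed without the 1 µM library 6 (0.0434). Too few fibroblast and leukocyte markers passed the filter for a test. Of 4 fibroblast markers the collagen gene COL1A1, which the matrix list also holds, rose by 2.60 at 10 µM (adjusted p = 0.0218), and FAP was at -0.75 (adjusted p = 0.314, with the block 7.18e-04). The only leukocyte marker kept, CSF1R, was at -0.05 (adjusted p = 0.823).

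At 5 µM the leading genes were largely those of the highest dose. PTGES rose by 3.59 ± 0.23 to 1508 ± 475 recovered counts (n = 3), FGFBP1 by 3.5, ACKR3 by 3.30, PAPPA by 3.28 and RDH10 by 3.20. Falls on the stabilised scale were MMP1 (-3.06 ± 0.30, adjusted p = 9.15e-05; 19.6-fold in recovered counts), DEPP1 (-2.97; 20.4-fold), TRIM55 (-2.63), KISS1 (-2.50) and SUN3 (-2.29). Limma called 1362 genes higher and 1322 lower than in vehicle (215 and 128 by at least 1), and the replicate block 2712 and 2724. Counts of higher and lower genes were 827 and 810 without vehicle 8, 853 and 761 without vehicle 11, 883 and 821 without the 5 µM library 6, 848 lower without the 5 µM library 8, 2485 and 2454 without number 6, 81 and 56 without number 8, and 112 and 93 without number 11.

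At 1 µM PTGES again rose most on the stabilised scale, by 2.63 ± 0.23 (adjusted p = 2.36e-04) to 743 ± 190 recovered counts. DNER, a Notch ligand (chromosome 2, 229357629 to 229714558), rose 4.99-fold from 1268 ± 138 to 6319 ± 685 counts (2.27 ± 0.13, adjusted p = 9.27e-06), followed by RDH10 (2.23), PAPPA (2.08) and SECTM1, a transmembrane protein of immune and epithelial cells (2.06). MMP1 (-1.79 ± 0.30), PTPRR (-1.27), the semaphorin receptor PLXNA2 (-1.13), NAV2 (-1.10) and PODXL (-1.10) fell, each in 3 of 3 label numbers.

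At this dose limma called 210 genes higher and 109 lower (46 and 7 by at least 1), a split that depended on the method. Voom on the recovered reads gave 174 higher and 226 lower, while limma on log2 of recovered counts plus 1 gave 239 and 97. The replicate block gave 1201 and 934. Counts of higher and lower genes were 405 and 300 without vehicle 6, 72 and 28 without vehicle 8, 85 and 33 without vehicle 11, and 113 and 58, 79 and 29, and 86 and 38 without the 1 µM libraries 6, 8 and 11. They were 1200 and 973 without number 6, 4 and 0 without number 8, 2 and 0 without number 11, and 67 lower without the 5 µM library 8.

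**Figure D4:**
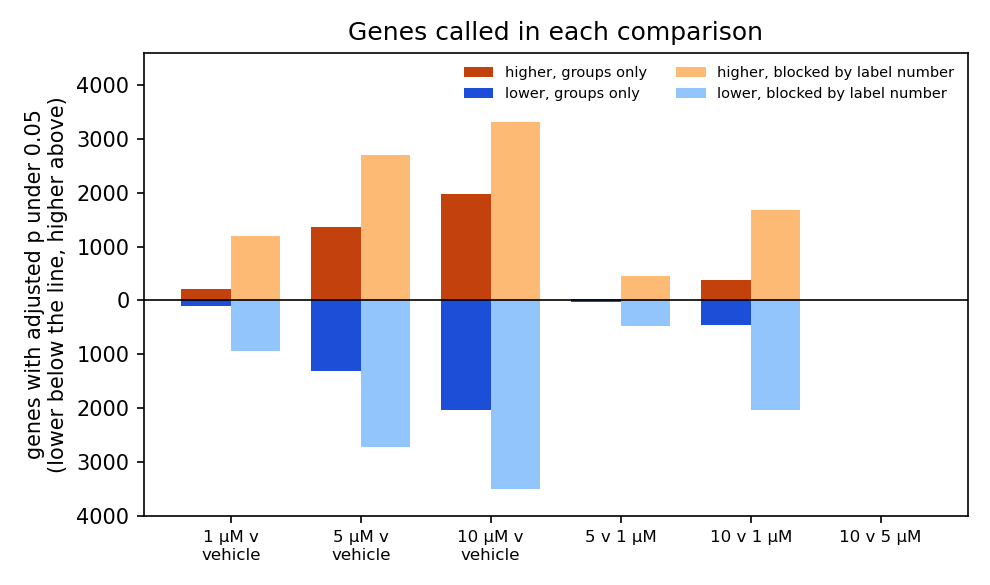
Number of genes (y axis) called higher or lower by limma (adjusted p under 0.05) in each comparison between doses (x axis), for the unblocked fit and for the fit with the label number as a replicate block. Bars start at 0; at 10 µM against vehicle they reach 1982 higher and 2033 lower unblocked and 3326 and 3498 blocked.

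Between 1 and 5 µM, 34 genes rose and 21 fell. TRIM16L, whose sequence is close to that of TRIM16 and which is uncertain for that reason, rose by 1.58 ± 0.14 (adjusted p = 6.18e-04), and PAPPA by 1.20 ± 0.20, with the overlapping PAPPA-AS1 at 1.29. TXNRD1, the cytosolic thioredoxin reductase, rose by 1.10 ± 0.17 (adjusted p = 0.0164). ROBO4 fell by 1.10, PODXL by 0.93 and NAV2 by 0.92, as did MT1E (-0.93), a metallothionein with close paralogs and uncertain for that reason. The block gave 446 higher and 476 lower. Counts of higher and lower genes were 57 and 47 without vehicle 6, 8 and 4 and 18 and 9 without the 1 µM libraries 8 and 11, and 15 and 7 and 12 and 8 without the 5 µM libraries 6 and 8. There were 10 lower without the 1 µM library 6, 21 higher without the 5 µM library 11, 32 lower without the 10 µM library 6, 278 and 251 without number 6, and 0 and 0 without number 8 or number 11.

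Between 1 and 10 µM, 386 genes rose and 451 fell, and a median shift of the libraries gave 501 and 338. IGFBP3 rose by 2.73 ± 0.54, FGFBP1 by 2.43, ABCC3 by 2.20, SCG2 by 2.10 and LPAR1 by 2.09. PAEP, a secreted glycoprotein of the reproductive tract also known as glycodelin, fell (-2.54 ± 0.61, adjusted p = 0.0373), as did SIGLEC15, a sialic acid receptor (-1.79), the integrin chain ITGB3 (-1.43) and the neurotensin receptor NTSR1 (-1.40). The block gave 1681 higher and 2032 lower. Counts of higher and lower genes were 608 and 813 without vehicle 6, 244 and 281 without vehicle 8, 195 and 188, 68 and 78, and 103 and 129 without the 1 µM libraries 6, 8 and 11, and 96 and 113, 235 and 229, and 212 and 291 without the 10 µM libraries 6, 8 and 11. There were 280 lower without the 5 µM library 8, 934 and 1189 without number 6, and 0 and 0 without number 8 or number 11.

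Between 5 and 10 µM limma called 0 genes in either direction, with 601 genes at an unadjusted p under 0.05. Voom on the recovered reads also called 0, and voom with the replicate block called 13 higher and 3 lower. The blocked limma fit called 1 gene, ALOX5AP, which helps make leukotrienes and which was named after its values were seen; it was lower at 10 µM than at 5 µM (-0.60, adjusted p = 0.00611 with the block).

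Over all groups 2634 genes differed among the 4 doses and, over dose rank, 2249 rose and 2306 fell (5980, 3646 and 3796 with the block). The genes that differed numbered 1502 without vehicle 8, 1587 without vehicle 11, 4693 without number 6, 61 without number 8 and 136 without number 11, and the genes rising and falling numbered 570 and 481 without number 8 and 685 and 819 without number 11. PTGES and PAPPA were among the genes with the largest rises at each dose on the stabilised scale and MMP1 among the largest falls.

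Calls were shared between doses. Of the 210 genes higher at 1 µM, 208 were also higher at 5 µM (independent lists would share 16.1) and 206 at 10 µM (23.4). Of the 109 lower genes, 105 and 103 were also lower (8.11 and 12.5). At 5 and 10 µM, 1245 genes were higher in both (152) and 1212 lower in both (151), and 0 genes were called in opposite directions in any pair of doses. In 100 simulations of unchanged groups against the same vehicle libraries, 0 calls on average were shared between 1 and 5 µM or between 5 and 10 µM and 0.01 between 1 and 10 µM. Unchanged groups leave few calls to share. These counts therefore cannot show how many of the real shared calls come from the shared vehicle libraries. The correlation of differences across genes, which are not independent replicates, was 0.845, 0.754 and 0.943 for 1 and 5, 1 and 10, and 5 and 10 µM (simulated 0.499, 0.504 and 0.499). The covariances were 0.0755, 0.0786 and 0.147 against 0.0173, 0.0175 and 0.0173 simulated. The 3 vehicle libraries are too few to divide into sets of at least 2, so part of the excess over independent lists may come from the shared controls. The simulated correlations and covariances include the shared controls, and the independent lists leave them out.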

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

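The tests on depth, on treatment of vehicle library 6, on the step from vehicle 6 to 1 µM, on the change from 1 to 10 µM and on pseudogenes were chosen only after the results were seen; the others in this part were written beforehand.

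The slope over dose rank differed between the libraries of label number 6 and those of 8 and 11 in 8 gene lists, by a test of the difference itself. A test among all 3 numbers found 34 genes whose slope differed. The adjusted p was 5.96e-37 for G2/M and mitosis, 5.13e-30 for replication-dependent histones, 9.12e-20 for G1/S and DNA replication, 1.09e-07 for NF-kB and cytokines, 4.58e-06 for p53 targets, 3.82e-05 for glycolysis, 5.79e-04 for ovarian carcinoma markers and 0.00324 for cholesterol synthesis. With an estimated correlation these lists gave 0.334 to 0.578, so none of the 8 passed. Median slopes per dose step in numbers 6, 8 and 11 were -0.65, 0.07 and 0.11 for G2/M, -0.53, 0.02 and 0.08 for histones, -0.43, -0.16 and -0.15 for G1/S, 0.08, -0.07 and -0.10 for NF-kB and cytokines, and -0.01, -0.15 and -0.11 for p53 targets. They were -0.16, -0.01 and 0.02 for glycolysis, -0.24, -0.04 and -0.09 for ovarian carcinoma markers and -0.26, -0.17 and -0.12 for cholesterol synthesis. Of the 34 genes, 16 had a higher slope in number 6 and 18 a lower one, and limma found 0 genes that differed between 8 and 11. CENPE, a mitotic motor named here after its values were seen, was the only G2/M gene among them (adjusted p = 0.0393).

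The pattern weighed first was the fall of G2/M genes with dose in number 6 alone, which started from a vehicle library with a G2/M median of 11.2 against 9.20 and 8.80 and ended at 9.40 against 9.45 and 9.16 at 10 µM. The lower depth of vehicle library 6 was argued against by 12 G2/M genes with a mean value of 10 or more, where counting noise is small: vehicle 6 was above the mean of vehicle 8 and 11 by a median of 2.25 (12 of 12 genes, 1.09 to 2.87). The position of vehicle 6 between vehicle and 10 µM left a library mislabelled or treated at 1 µM or more undecided, at 0.303 over 6285 genes (quartiles -0.2 to 0.8) and 0.287 over the 200 genes that changed most in numbers 8 and 11. A further pair of tests argued against both as the cause. Over those 200 genes the median step from vehicle 6 to the 1 µM library 6 was 0.420 of the change (quartiles 0.275 to 0.585, 195 of 200 positive), against 0.499 and 0.536 in numbers 8 and 11, where the genes had been picked. With the vehicles set aside, the change of the G2/M genes from 1 to 10 µM differed between number 6 and the mean of 8 and 11 by a median of -1.34 (lower in 34 of 34 genes). These genes move together (estimated correlation 0.956) and each number has 1 library per dose, so they are not separate evidence. A lower exposure of vehicle 6 was not tested. What sets number 6 apart stays open, and neither a batch nor a biological explanation was tested, since the labels do not say what the number marks.

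The second pattern weighed was the fall of ribosomal protein genes, with a median of -0.73 at 10 µM. Of 10000 lists matched on transcript length and mean value, the lowest median was -0.20 (middle 95% -0.1 to 0.1). Each match was drawn from the 50 nearest genes, however far, and how near they came was not checked. Lists of genes drawn singly also vary less than a list whose members move together. Length and abundance as the whole cause were thus argued against only so far as the match was close. Scaling was argued against by a median of -0.64 with quantile normalisation and -0.72 with a median shift. Reads moved to pseudogenes were argued against by 93 ribosomal protein pseudogenes, whose median was -0.23 (16 lower, 2 higher) and which held 0.385% of their parents' reads. A lower output of ribosomal protein genes under the drug may be a hypothesis, found and tested on the same data, but reads that were not unique took a lower share than in the vehicle of the same number in 9 of 9 treated libraries and the 10 most abundant genes a higher one in 9 of 9, and neither these shifts nor a change in the yield of short or abundant RNAs was tested as a cause.

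Other splits of the libraries were counted for each result. The 10 splits of 6 libraries are too few for a share under 0.05. The real split called 319 genes at 1 µM, 2684 at 5 µM, 4015 at 10 µM, 55 for 5 µM against 1 µM, 0 for 10 µM against 5 µM and 837 for 10 µM against 1 µM, and the highest other split called 0 in each; with the real split included, 1 split, or all 10 for 10 µM against 5 µM, reached the real count. For gene lists the real split called 7, 7 and 8 at 1, 5 and 10 µM and the highest other 12, 13 and 10, with 7, 8 and 8 splits, the real one included, reaching the real count. The number of lists called by camera therefore did not set the real grouping apart from other groupings. The 4 splits per comparison that part all label numbers called, with the block, 2135, 5436, 6824, 922, 1 and 3713 genes when real and 0 otherwise. In 100 draws, the real grouping called 2634 genes for the 4 groups (highest other 2933) and 4555 for dose rank (3934 other). These draws moved libraries across label numbers and so left the pairing out. Draws within label numbers, with the block, gave 5980 real and 4970 other for the 4 groups, and dose rank had no such version. With the real grouping included, 2, 1 and 1 draws reached the real count, each a share under the 0.05 set beforehand. Thus 1 other draw did so for the 4 groups and 0 for the rest. That draw kept vehicle and 1 µM whole and mixed the 5 and 10 µM libraries.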

How the results depend on the processing

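The tests with voom, log2 of recovered counts plus 1, a random amount within the rounding step, and numbers 8 and 11 alone were chosen only after the data had been seen. Higher and lower counts are given in the order 1, 5 and 10 µM against vehicle, then 5 and 10 µM against 1 µM; where results moved, the cause was not tested. With array weights they were 2675 and 2451, 3829 and 3825, 3633 and 3761, 800 and 1030, and 1286 and 1477, with 8905 genes among the 4 groups, 3877 rising and 4000 falling with dose rank, and MYC at 1 µM at -0.37 (adjusted p = 0.00794). With the replicate block, which follows the pairing, they were 1201 and 934, 2712 and 2724, 3326 and 3498, 446 and 476, and 1681 and 2032, with 0 higher and 1 lower at 10 µM against 5 µM, 5980 among the groups, 3646 rising, 3796 falling and MYC at 1 µM at -0.37 (adjusted p = 0.0134). Every gene called without the block was called with it, and beyond the values given beside each result the block changed no other call of a list. A fit to 2 groups only, which has fewer samples, gave 29 and 19, 840 and 761, 1276 and 1277, 9 and 3, and 112 and 151. Camera with an estimated correlation called 0 lists at 1, 0 at 5 and 0 at 10 µM, and likewise 0, 0 and 0 with the block, where its lowest adjusted p was 0.397 and 0.175. Voom called 226 genes lower at 1 µM. Voom with the block called 910 and 1354, 2434 and 2930, 3687 lower at 10 µM, 595 and 439, and 1941 and 1735, with 13 higher and 3 lower at 10 µM against 5 µM, 5892 among the groups, 3849 falling and MYC at 1 µM at -0.41 (adjusted p = 0.00751). Numbers 8 and 11 alone with the block gave 1419 and 1155, 2656 and 2626, 3049 and 3236, 355 and 347, and 1107 and 1483, with 4924 among the groups, 3554 falling, 11 lists at 1 µM and MYC at 1 µM at -0.40 (adjusted p = 0.0159).

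Leaving out each library or label number gave ranges of 2 to 1200 higher and 0 to 973 lower at 1 µM, 81 to 2485 and 56 to 2454 at 5 µM, 347 to 2885 and 252 to 3050 at 10 µM, 0 to 278 and 0 to 251 for 5 µM against 1 µM, 0 to 934 and 0 to 1189 for 10 µM against 1 µM, and 0 to 0 for 10 µM against 5 µM. Genes among the groups ranged from 61 to 4693, rising from 570 to 3132 and falling from 481 to 3325, lists called from 5 to 10 at 1 µM and from 7 to 10 at 5 and 10 µM. MYC ranged from -0.48 to -0.28 at 1 µM, -0.75 to -0.53 at 5 µM and -0.93 to -0.58 at 10 µM. The fits that left out a library or label number used no block, so their counts do not allow for the pairing. No MYC value or named gene changed sign. The balance of higher and lower genes did change side, as at 10 µM without number 8 (347 and 252) or with a median shift (2024 and 1887), at 5 µM with voom (1284 and 1587), and for 10 µM against 1 µM with voom (431 and 380) or without the 1 µM library 6 (195 and 188) or the 10 µM library 8 (235 and 229). The direction of camera's calls for the G2/M and histone lists at 10 µM depended on the libraries: without number 6 they were called higher (adjusted p = 0.00199 and 0.0242) and without vehicle 11 lower (0.00238 for both). All 60 results of named genes passed with no filter, the stricter filter, array weights, the block, the added rounding amount, numbers 8 and 11 alone, voom with the block, and without number 6; 13 missed the threshold in the fit to 2 groups, 2 without the variance trend, 5 with the robust variance, 1 with quantile normalisation, 1 with a median shift, 5 with voom, 4 on log2 of recovered counts, 2 to 15 without a single library and 43 without number 8 or number 11. The test recovered 28.6% of simulated changes of 0.5 (log2) at 1 µM, so many changes of this size would be missed. At the same depth the replicate block called 1201 higher and 934 lower at 1 µM, against 210 and 109 without it. The spread between label numbers thus limits the unblocked calls, and whether depth also does was not tested. The added rounding amount left 206 higher and 103 lower at 1 µM.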

Other observations

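The test of the NRF2 targets that had not been seen was written before its result, while the idea itself, the first set of genes and the lists as a whole were chosen only after the data had been seen.

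Signalling and inflammatory genes moved in both directions at 10 µM, as genes did in general. Among all 17767 genes 1982 rose and 2033 fell at this dose (3326 and 3498 with the block). Counts near that share, in this and the following lists, do not set a list apart from other genes. Of 23 NF-kB and cytokine genes 6 rose and 3 fell (6 and 4 adjusted over the list alone; 8 and 9 with the block). The cytokines IL6 (2.43 ± 0.19), IL1B (1.63 ± 0.20) and LIF (1.13 ± 0.14) rose, and MMP1 fell. The chemokine CXCL3 was at -0.75 (adjusted p = 0.0897, with the block 0.0325). The list had a median of -0.10, a mean of 0.14 and an upward test (camera adjusted p = 0.913). Of 21 genes of MAPK output 6 rose and 3 fell (7 and 4 adjusted over the list alone; 11 and 8 with the block; camera adjusted p = 0.745): IER3 (0.90) and the phosphatase DUSP4 (1.28) rose, while the AP-1 subunit FOSL1 (-0.80) and SPRY4 (-1.0) fell. DUSP6 was at -0.53 (adjusted p = 0.0703, with the block 7.05e-05). Of 25 YAP/TEAD targets 8 rose and 2 fell (11 and 3 adjusted over the list alone; 12 and 6 with the block; 0.362), with the growth factor TGFB2 (1.42) and AMOTL2 (0.50) higher, the receptor kinase AXL (-0.70) lower and AMOTL1 at 0.23 (adjusted p = 0.0546, with the block 0.00553); at 5 µM the list passed without vehicle 6 (0.0455) or number 6 (0.0372). Of 19 SRF/MRTF genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; 2 and 5 with the block; 0.553), with CNN2 higher (0.50), FHL1 (-0.50) lower and MYL9 at -0.60 (adjusted p = 0.0894, with the block 4.28e-04). Of 25 interferon response genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; 6 and 10 with the block; 0.562), with IRF1 higher (0.83), the antiviral genes OAS3 (-0.95), IFI16 (-0.90) and IFIH1 (-0.47) lower and IFI44 at -1.19 (adjusted p = 0.0513, with the block 1.37e-05).

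Metabolic, stress and identity genes also divided at 10 µM, where 1982 of all 17767 genes rose and 2033 fell. In the integrated stress response 3 of 23 rose and 0 fell (3 and 0 adjusted over the list alone; 7 and 3 with the block; camera adjusted p = 0.356): the cystine carrier SLC7A11 (2.27 ± 0.38), DDIT4 (1.20) and SLC7A1 (0.40), with SLC3A2 at 0.77 (adjusted p = 0.109, with the block 2.77e-05). At 1 µM camera gave 0.144 for this list, which passed with the block (0.00100) and without vehicle 8 (0.0200), vehicle 11 (0.00956), the 1 µM library 6 (5.89e-05) or number 6 (2.01e-04). With an estimated correlation it gave 0.896 at 1 µM, and 0.229 with the block. It passed at 5 µM without vehicle 11 (0.0392) or the 5 µM library 6 (0.0110) and at 10 µM without the 10 µM library 6 (0.0356). Of 22 glycolysis genes 1 rose and 4 fell (2 and 4 adjusted over the list alone; 3 and 6 with the block; 0.473), with the lactate exporter SLC16A3 higher (1.17) and the hexokinases HK1 (-0.83) and HK2 (-1.07) lower and PFKP at 0.27 (adjusted p = 0.0505, with the block 0.0144); at 5 µM the list passed without vehicle 8 (0.0237), vehicle 11 (0.0491), the 5 µM library 11 (0.0423) or number 11 (0.0150). Of 16 heat shock genes 1 rose and 2 fell (0 and 2 adjusted over the list alone; 3 and 5 with the block; 0.682), with the mitochondrial chaperones HSPD1 (-0.50) and HSPE1 (-0.33) lower, HSP90AB1 at -0.23 (adjusted p = 0.0792, with the block 0.0187), a median of 0.02 and a mean of -0.04.

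Of 12 epithelial markers 3 rose and 3 fell (3 and 3 adjusted over the list alone; 4 and 4 with the block; camera adjusted p = 0.801), with desmoplakin (DSP, -0.96) and the keratins KRT8 (-0.83) and KRT18 (-0.73) lower and OCLN at 0.39 (adjusted p = 0.248, with the block 0.00412). Of 9 ovarian carcinoma markers 2 rose and 2 fell (2 and 2 adjusted over the list alone; 2 and 4 with the block; 0.486), with the lineage factor PAX8 (0.70) higher, the repair gene BRCA2 (-1.04) lower and BRCA1 at -0.47 (adjusted p = 0.106, with the block 0.0211). Of 16 circadian clock genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; 5 and 1 with the block; 0.623), with the repressor BHLHE40 (-0.67) lower, BHLHE41 (0.96) higher and DBP at 0.31 (adjusted p = 0.139, with the block 0.0191). TUG1 (0.23) was the only 1 of 8 nuclear and non-coding RNAs called (1 adjusted over the list alone; 3 higher and 2 lower with the block; camera adjusted p = 0.940), with KCNQ1OT1 at 1.80 (adjusted p = 0.0913, with the block 5.30e-08), a median of -0.18, a mean of 0.04 and an upward test. Limma called 0 of 13 mitochondrially encoded genes at 10 µM over all genes or over the list alone, with 0 at an unadjusted p under 0.05 and 0 by voom (camera adjusted p = 0.902; MT-ND3 at 0.23, adjusted p = 0.278), and the list was called lower at 1 µM without vehicle 11 (0.0157), the 1 µM library 6 (0.00672) or number 8 (0.0309).

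Several of the genes called between 1 and 5 µM are targets of NRF2, a transcription factor of the antioxidant response, which raised the hypothesis that this programme rises between these doses. The 19 tested targets outside the set seen first had a median difference of 0.40 for 5 µM against 1 µM (0.60, 0.30 and 0.40 in numbers 6, 8 and 11). Camera gave unadjusted p = 8.26e-12, and unadjusted p = 0.00292 with an estimated correlation (0.0127 with the block). The p-values of the lists fixed beforehand were adjusted over all their tests, so the values here cannot be compared with them. They do not show that this list would pass where those lists failed with an estimated correlation. Limma called 1 of the 19 (10 with the block): PGD of the pentose phosphate pathway (0.57, adjusted p = 0.0298), while the quinone reductase NQO1 was at 1.03 (adjusted p = 0.0535, with the block 0.00410), HMOX1 at 0.40 (adjusted p = 0.446, with the block 0.0221), and AKR1C1, which has close paralogs and is uncertain, at 0.76 (adjusted p = 0.0535, with the block 0.00665). Against vehicle 0, 10 and 12 of the 19 rose at 1, 5 and 10 µM and 0, 0 and 1 fell. Between 5 and 10 µM limma called 0 of the 19. Camera placed the list higher there too (median 0.13, unadjusted p = 7.24e-06, and unadjusted p = 0.0244 with an estimated correlation). The rise was thus not shown to be confined to the step from 1 to 5 µM. The 13 genes seen first had a median of 1.01 with 11 called, and are no test of the idea. A rise of NRF2 targets between 1 and 5 µM may be kept as a hypothesis; protein levels of NRF2 and oxidative stress were not analysed here.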
